A study of Homo sapiens with 12 samples.

How the data were processed

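RNA was measured by sequencing in MCF7 cells, an established human breast adenocarcinoma line that carries the estrogen receptor and depends on estradiol for growth. The 12 libraries form 6 groups of 2: control siRNA (siCont), BRD4 siRNA (siBRD4) or the bromodomain inhibitor JQ1, each with vehicle (Veh) or 17-β-estradiol (E2). Per the labels' protocols, the cells were deprived of hormone for 2 days in medium with 5% charcoal-stripped serum, and E2 was given at 10 nM for 2 h. JQ1 was added at 150 nM, 30 min before E2, to cells that also carried the control siRNA. RNA was taken with Trizol, and 500 ng per library went into Illumina TruSeq RNA libraries. The labels do not say whether the duplicates were separate cultures, so all p-values measure the spread between these libraries alone.

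The deposited table gives, for each gene symbol and library, a read signal normalised by the authors. Reads were aligned with Bowtie2 2.1.0 to hg19 and normalised with DESeq 1.14.0, per the submitters' processing notes. The program that counted reads and the gene annotation are not given in the sources used here, nor is a strand setting, so antisense and overlapping genes cannot be told apart. In each column, 100% of the values were whole multiples of 1 step within a tolerance of 0.01 (largest deviation 5.8e-10), so whole reads were recovered as value divided by step. These totals ran from 20969671 to 32899564 reads per library. The table has 26504 entries, 1 of which is named unknown and held at most 0.000334% of a library. It was left out. The columns name the treatment and a letter, a or b, which was not matched to the replicate numbers of the sample titles, so libraries are named here by group and letter. The columns for vehicle were taken as those whose names lack the word plus.

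Values were analysed as log2(normalised count + 1) with limma 3.58.1 in R 4.3.3: 1 linear model with 6 group means, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. The 16490 genes with a mean normalised count of at least 10 over the 12 libraries were tested. The comparisons were E2 against vehicle within each treatment, each treatment against control siRNA within vehicle and within E2, and the 3 differences between E2 responses (interaction terms). E2-induced genes were those called in control siRNA with a rise of at least 1.5-fold. For these, the median difference of the E2 response was taken without a p-value, because the same control libraries chose the genes and entered the difference. The tests, the gene lists and the rule for naming genes were fixed before the data were examined.

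The rule named, in each comparison, BRD4, BRD2, BRD3, ESR1, HEXIM1, MYC, GREB1, TFF1, PGR and CCND1. It also took the 10 highest and 10 lowest called genes by log2 fold change among those with a mean normalised count of at least 50 and no overlap between the libraries compared. Up to 4 called members of each gene list were added. Of these, about 20 to 30 per comparison are named, in order of absolute change. A called gene named in a comparison of 2 groups therefore differed in the same direction in all 4 libraries, except list members and the 10 genes always named, for which this was not required.

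The 19 gene lists held 367 genes: estrogen-induced, estrogen-repressed, immediate-early, BET family with P-TEFb, histone and other BET-inhibitor genes, luminal identity, estrogen receptor coregulators, ribosome biogenesis, DNA replication, mitosis, p53 targets, interferon response, cholesterol synthesis, ATF4 and endoplasmic reticulum stress, NF-kB and inflammation, hypoxia and glycolysis, markers of other cell types, mitochondrial mRNA, and ribosomal proteins. Lists were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated per list, with adjustment over the 19 lists of a comparison. List members absent from the table, among them FOXA1, IFIT1, IFIH1, MCM3, MCM6 and ZFP36, were not analysed here.

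One library, JQ1_E2 a, stood apart from its partner. Counts are therefore given for all 12 libraries and, as an addition chosen after the data were seen, without it (16479 genes tested). That second fit leaves JQ1_E2 with 1 library, which is then assumed to vary like the libraries of the other groups. The direct contrasts of JQ1 with BRD4 siRNA were added after the data were seen as well.

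Alternatives covered the pseudocount, the filter, TMM and upper quartile scaling, each library left out in turn, fits of the compared groups alone, eBayes without trend, sample weights, a replicate block by column letter, removal of a trend with transcript length, and tests on recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald). Transcript lengths and GC content were medians over the GENCODE transcripts of each gene symbol, with older symbols matched through RefSeq synonyms. Gene neighbours came from a RefSeq table of GRCh38, matched by symbol, and no coordinates are given because the reads were aligned to hg19. Overlaps of calls are printed beside the overlap of independent lists of the same sizes. Chance correlations came from 100 simulated draws of unchanged groups that share the control libraries, with the spread of each gene in the fit without JQ1_E2 a.

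The limma step was tested on simulated counts for E2 in control siRNA, with 12 libraries alike (16443 genes). It recovered 79.1% of genes changed by 1.5-fold, 88.1% at 2-fold and 100% at 4-fold, with 11 false calls. When 1 library was given extra spread (16433 genes), it recovered 13.4%, 55.2% and 95.5%, with 0 false calls. Leaving that library out (16435 genes) gave 83.6%, 92.5% and 100%, with 15 false calls. Genes with near-identical copies, such as the replication-dependent histone genes, the FCGR1 genes and HBA1 with HBA2, are uncertain because the counting could split their reads. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.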

Results

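RNA was sequenced from hormone-deprived MCF7 cells after a 2 h pulse of 10 nM estradiol or vehicle, with BRD4 either depleted by siRNA or displaced from acetylated chromatin by JQ1. BRD4 is a bromodomain protein of the BET family that recruits the elongation factor P-TEFb. The series asks whether estrogen receptor target genes need it. Each of the 6 groups had 2 libraries. Read totals of libraries a and b were 26879004 and 20969671 in siCont_Veh, 32230506 and 27420550 in siCont_E2, 22828631 and 22020690 in siBRD4_Veh, 25568277 and 25205300 in siBRD4_E2, 32899564 and 31367741 in JQ1_Veh, and 32076786 and 29794976 in JQ1_E2. Between 19672 and 20469 genes had at least 1 read per library.

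BRD4 mRNA fell under its siRNA in every library. The normalised read count was 2792 ± 164 (SD, n = 2) in siCont_Veh and 2923 ± 179 in siCont_E2, against 834.1 ± 21.6 in siBRD4_Veh and 824.6 ± 17.4 in siBRD4_E2. The limma log2 difference over both hormone states was -1.78. JQ1 left BRD4 at 2602 ± 144 in vehicle. In JQ1_E2 it was 1569 in library a and 2484 in library b. HEXIM1, which codes for the inhibitor of P-TEFb and rises when BET bromodomains are blocked, went from 2549 in siCont_Veh to 7243 in JQ1_Veh and 6346 in JQ1_E2, and fell to 996.1 in siBRD4_Veh.

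**Figure D1:**
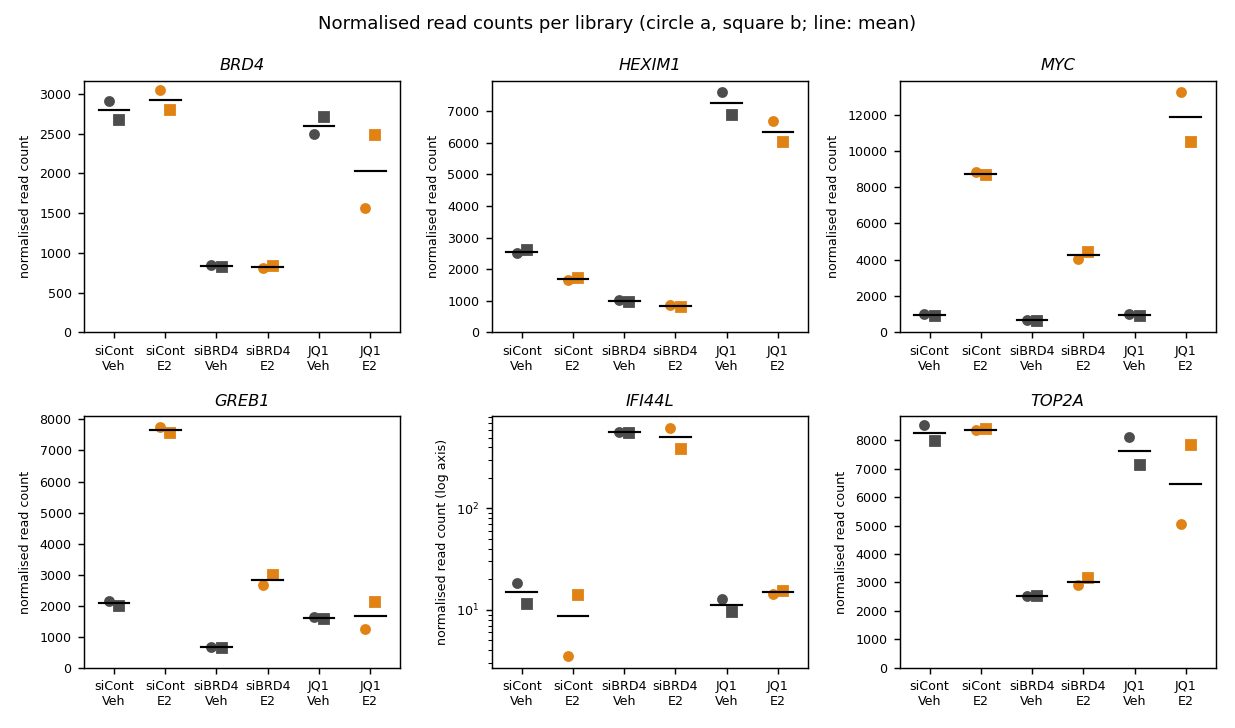
Normalised read count per library of BRD4, HEXIM1, MYC, GREB1, IFI44L and TOP2A in the 6 groups (circle library a, square library b, line the mean). BRD4 lies at 834.1 and 824.6 in the siBRD4 groups against 2792 and 2923 in control siRNA, and GREB1 reaches 7650 with E2 in control siRNA but 1677 with E2 under JQ1. The IFI44L axis is logarithmic.

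The libraries of 5 groups correlated with their partners at r = 0.995 to 0.996 across genes, while the JQ1_E2 pair had r = 0.967. The SD of the log2 difference between partners was 0.248 to 0.27 in the other 5 pairs and 0.736 in JQ1_E2. Short transcripts were higher in library a and long ones lower, and all 20 measured ribosomal protein genes were higher in a, by a median log2 difference of 1.08. Because the fit shares 1 spread over all groups, the median standard error of the E2 response in control siRNA was 0.192 with this pair and 0.0988 without JQ1_E2 a. Both JQ1_E2 libraries also held transcripts of blood and fat tissue that were near absent elsewhere. HBB stood at 363.7 and 575.3, and FABP4 at 388.4 and 583.5, against at most 3.85 and 2.59 in the other 10 libraries.

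**Figure D2:**
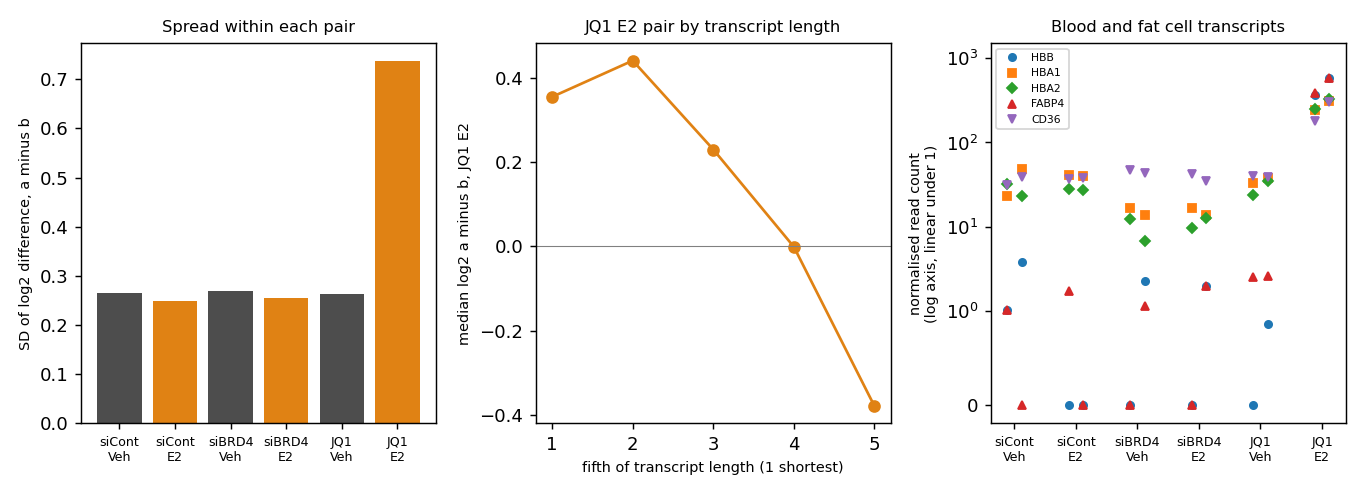
Left, SD of the log2 difference between the libraries of each pair. Middle, median log2 difference a minus b in JQ1_E2 over 5 bins of transcript length, from 0.36 in the bin of shortest to -0.38 in that of longest transcripts. Right, normalised read count of HBB, HBA1, HBA2, FABP4 and CD36 in each library on a log axis that is linear under 1, highest in both JQ1_E2 libraries.

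Estradiol changed control cells within 2 h, and more genes rose than fell. The potassium channel gene KCNK5, the chemokine gene CXCL12, the progesterone receptor gene PGR and the transcription factor genes EGR3 and MYC rose by at least 8-fold. The hormone also lowered RGS2, which damps G-protein signalling, the stress gene DDIT4 and the cyclin gene CCNG2. The receptor of estradiol acts by binding DNA, which was not measured here, and PGR, GREB1 and CCND1 are long-known targets. In numbers, 624 of 16490 genes changed (limma), 432 higher (69.2%) and 192 lower, with 210 and 50 of them by at least 2-fold. Without JQ1_E2 a, 2809 genes were called, 1565 higher and 1244 lower, and these held all 624. Leaving out JQ1_E2 b gave 2800 genes, and leaving out siCont_Veh a, siCont_Veh b, siCont_E2 a or siCont_E2 b gave between 236 and 269.

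KCNK5 rose from 72.8 ± 9.45 to 1666 ± 66.5 normalised reads (SD, n = 2), a log2 fold change of 4.5 ± 0.2 (SE). CXCL12 rose by 3.78 ± 0.27, PGR by 3.68 ± 0.35, the endothelial receptor-like gene HEG1 by 3.38 ± 0.27, the RNA-binding protein gene RBM24 by 3.36 ± 0.19, EGR3 by 3.24 ± 0.13 and the kinase gene SGK1 by 3.12 ± 0.21. MYC went from 977.8 to 8753, a log2 fold change of 3.16 ± 0.13 with limma adjusted p = 2.68e-06. FOS rose by 2.47, the receptor cofactor gene NRIP1 by 2.07, the luminal transcription factor gene XBP1 by 2.05, GREB1 by 1.88 and the cyclin gene CCND1 by 1.75. TFF1 rose by 1.28 ± 0.36 and was not called (adjusted p = 0.0945), though it was without JQ1_E2 a (adjusted p = 1.55e-08). On the falling side, RGS2 changed by -2.48 ± 0.27, the dopamine receptor gene DRD1 by -2.12, the zinc finger gene ZIC3 by -2.04, the decoy receptor gene TNFRSF11B by -1.88, DDIT4 by -1.66, the Wnt antagonist gene RNF43 by -1.65 and CCNG2 by -1.35.

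Of 38 estrogen-induced genes measured, 32 rose and 0 fell, and 36 were called when adjusted over the list alone (median log2 fold change 1.58, 38 of 38 positive). Camera gave the list an adjusted p = 1.62e-64, and adjusted p = 0.0011 with an estimated correlation. Of 17 estrogen-repressed genes, 8 fell and 1, KLF4, rose, with 10 called when adjusted over the list alone (camera adjusted p = 1.77e-08, and adjusted p = 0.0148 with an estimated correlation). TXNIP fell by 1.16, TP53INP1 by 1.06 and the receptor-signalling gene SMAD6 by 1.28. In ribosome biogenesis 11 of 25 genes rose and 0 fell, 14 when adjusted over the list alone, with RCL1 at 1.1, RRS1 at 1.09, the RNA polymerase I gene POLR1B at 1.03 and NIP7 at 0.80. Camera gave adjusted p = 1.2e-17, and adjusted p = 0.104 with an estimated correlation. SLC2A1 rose by 1.72 and PFKFB3 by 1.95, in a hypoxia and glycolysis list with 4 of 15 up and 1 down (5 when adjusted over the list alone, camera adjusted p = 0.0354, and adjusted p = 0.414 with an estimated correlation). The p53 target list had 4 of 18 down, BTG2 by -0.96 and SESN2 by -0.75 among them (6 when adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.121 with an estimated correlation). The immediate-early list split, with 3 of 21 up and 2 down. Among the markers of other cell types, VWF rose by 2.48 and COL1A1 by 0.75.

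The E2 response under BRD4 siRNA asks what remains when BRD4 is depleted. ESR1, the gene of the estrogen receptor, was itself lower under BRD4 siRNA in vehicle and with E2. A smaller response through less receptor therefore cannot be told apart from a need for BRD4 at the target genes. KCNK5, PGR, MYC, GREB1 and XBP1 still rose at least 4-fold, but the 368 genes induced in control siRNA went from a median log2 fold change of 1.1 to 0.46. In numbers, 88 genes changed (limma), 87 higher (98.9%) and 1 lower, and 85 of the 87 were among the 432 that rose in control siRNA, against 2.28 for independent lists. The log2 fold changes of both settings correlated across genes with r = 0.541. Without JQ1_E2 a, 517 genes were called, 345 higher and 172 lower, and they held all 88. Leaving out JQ1_E2 b gave 522, and leaving out siBRD4_Veh a, siBRD4_Veh b, siBRD4_E2 a or siBRD4_E2 b gave 39 to 50.

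KCNK5 rose by 4.31 under BRD4 siRNA, but from 29.7 to 604.1 normalised reads, under its level with E2 in control cells. PGR rose by 3.46, RBM24 by 3.45, the potassium channel gene KCNF1 by 3.43, the Notch effector gene HEY2 by 2.91, MYC by 2.67 and FOXC1 by 2.47. GREB1 rose by 2.07 and XBP1 by 2.03. Smaller rises were seen for NRIP1 at 1.38, EGR3 at 1.38, FOS at 0.87 and SLC2A1 at 0.71. The 1 gene that fell was SMAD6, by -0.83. Of the 38 estrogen-induced genes 19 rose and 0 fell, 31 when adjusted over the list alone (camera adjusted p = 3.68e-98, and adjusted p = 0.00032 with an estimated correlation). The estrogen-repressed list had 1 of 17 down, 5 when adjusted over the list alone (camera adjusted p = 2.88e-06, and adjusted p = 0.0335 with an estimated correlation). No ribosome biogenesis gene was called by limma, though camera gave the list adjusted p = 5.92e-10, and adjusted p = 0.317 with an estimated correlation.

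Under JQ1, estradiol still raised MYC, while GREB1 was not called and depends on the library. MYC, the Notch effector HEY2 and the extracellular regulator gene TSKU rose strongly. GREB1, a receptor cofactor and standard estrogen target, changed by 0.01, by 0.4 without JQ1_E2 a and by -0.38 without b. The blood and fat transcripts HBB, FABP4, HBA1, HBA2 and CD36 rose with this group, whose libraries held these transcripts apart from any hormone response seen in other cells. In numbers, 219 genes changed (limma), 156 higher and 63 lower. Of these, 136 also rose and 48 also fell in control siRNA, against 4.09 and 0.734 for independent lists, with r = 0.379 across genes. Without JQ1_E2 a, 784 genes were called, 457 higher and 327 lower, and 218 of the 219 were among them. Without JQ1_E2 b the count was 10122, which compares the library that stands apart, alone, with JQ1_Veh. It was 56 without JQ1_Veh a, 58 without JQ1_Veh b, and 115 to 133 without any 1 of the 8 libraries of the other groups. With only the compared groups in the fit, 3 genes were called, and with sample weights 41.

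MYC rose from 933.9 to 11860 normalised reads, by 3.66 ± 0.13 on the log2 scale. KCNK5 rose by 2.78, TSKU by 2.73, HEY2 by 2.68, the potassium channel gene KCNK6 by 2.55, XBP1 by 2.11, MYB by 2.03, STC2 by 2.00, PGR by 1.93 and CCND1 by 1.44. GREB1 stayed at 1608 in vehicle and 1677 with E2, a log2 fold change of 0.01 (adjusted p = 0.982). Its libraries differed, at 1235 in a and 2119 in b, and without JQ1_E2 a, with b alone in its group, the change was 0.4. EGR3 rose by 1.06, FOS by 0.91 and SLC2A1 by 1.02. The nucleolar genes RRS1 and BYSL rose by 1.26 and 1.19 (0.97 and 0.89 without JQ1_E2 a). On the falling side were the cholesterol exporter gene ABCA1 at -1.46, the actin-binding protein gene ENC1 at -1.83, ZIC3 at -1.29, DDIT4 at -1.20, CCNG2 at -1.10 and TXNIP at -0.95. The size for ABCA1 leans on library a, with 231.2 in JQ1_E2 a and 499.1 in b against 934.5 in JQ1_Veh. Of the estrogen-induced genes 19 rose and 0 fell, 26 when adjusted over the list alone (camera adjusted p = 2.78e-26, and adjusted p = 0.0137 with an estimated correlation). The estrogen-repressed list had 5 of 17 down and 1 up, 10 when adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.178 with an estimated correlation). Ribosome biogenesis had 4 of 25 up, 19 when adjusted over the list alone (camera adjusted p = 6.83e-12, and adjusted p = 0.23 with an estimated correlation). Without JQ1_E2 a 10 of 25 rose (camera adjusted p = 5.72e-22, and adjusted p = 0.112 with an estimated correlation).

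Whether the E2 response itself differed was tested by interaction terms and by the shift of E2-induced genes. The 368 E2-induced genes had a median log2 fold change of 1.1 in control siRNA, 0.46 under BRD4 siRNA and 0.61 under JQ1. The median difference from control was -0.58 under BRD4 siRNA, with 344 of 368 genes lower, and -0.51 under JQ1, with 335 lower (SD 0.03 over the combinations of single libraries). In the list of estrogen-induced genes fixed in advance, which the control libraries did not choose, the medians were -0.48 under BRD4 siRNA and -0.47 under JQ1. That list had 12 and 14 members called when adjusted over the list alone, with camera adjusted p = 9.98e-20 under BRD4 siRNA and 4.26e-15 under JQ1, and adjusted p = 0.0294 and 0.0583 with an estimated correlation. The estrogen-repressed list shifted upward under BRD4 siRNA, by a median of 0.45 with 5 members called when adjusted over the list alone (camera adjusted p = 2.85e-06, and adjusted p = 0.0353 with an estimated correlation). Ribosome biogenesis genes had a median difference of -0.36 under BRD4 siRNA, with 0 of 25 called by limma (camera adjusted p = 5.47e-11, and adjusted p = 0.159 with an estimated correlation), and of 0.03 under JQ1 (camera adjusted p = 0.437, and adjusted p = 0.832 with an estimated correlation). The value under JQ1 averages libraries that differ in these genes, by a median a minus b of 0.372 with 20 of 25 higher in JQ1_E2 a.

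**Figure D3:**
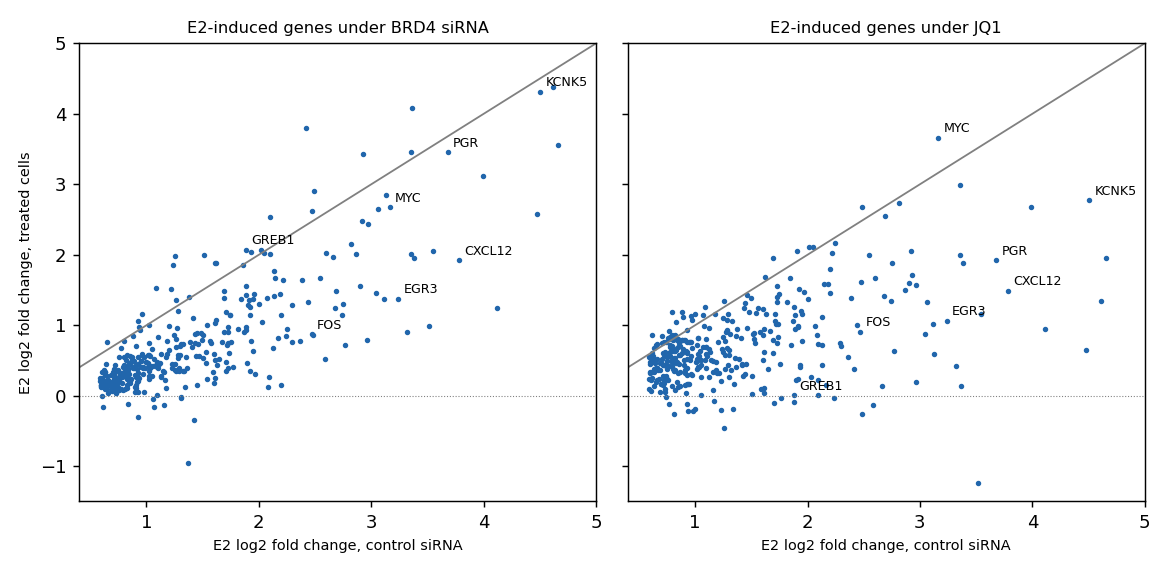
E2 log2 fold change of the 368 E2-induced genes in control siRNA (x axis) against that under BRD4 siRNA (left) and under JQ1 (right). Points under the grey line, where both changes are equal, rose less in treated cells: 344 under BRD4 siRNA and 335 under JQ1. MYC lies above the line under JQ1 and GREB1 near 0.

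Gene by gene, the immediate-early transcription factor gene EGR3 lost most of its induction. Its normalised reads went from 104.8 to 997.4 with E2 in control siRNA, from 55 to 144.6 under BRD4 siRNA and from 84.8 to 178.5 under JQ1. It was the 1 gene whose E2 response differed under BRD4 siRNA among all 12 libraries (interaction -1.86), where 704 genes had an unadjusted p under 0.05. DESeq2 called 66 genes. Under JQ1, 9 genes were called (708 at an unadjusted p under 0.05, 62 by DESeq2), among them EGR3 at -2.17, the transglutaminase gene TGM2 at -2.26, the Wnt receptor gene FZD7 at -1.57, FOS at -1.56 and MYBL1 at -1.55. Without JQ1_E2 a, 644 genes differed under BRD4 siRNA, 187 higher and 457 lower. Under JQ1 162 differed, 18 higher and 144 lower. With only the compared groups in the fit 649 genes differed under BRD4 siRNA and 1 under JQ1, and with sample weights 657 and 3. The sets without JQ1_E2 a include CXCL12 at -1.86 under BRD4 siRNA and -2.33 under JQ1, SGK1 at -1.75 and -2.04, FOS at -1.6 and -1.75 and SLC2A1 at -1.01 and -0.81. RGS2, at 2.22, and ZIC3, at 1.45, fell less with E2 under BRD4 siRNA. RGS2 was already low there without E2, at 16.3 normalised reads against 134.8 in siCont_Veh and 23.5 in siCont_E2, and stood at 13.7 with E2. Leaving out JQ1_E2 b gave 643 genes under BRD4 siRNA and 8441 under JQ1, the latter with library a alone in its group. The count was 0 under BRD4 siRNA without any 1 library of the other 5 groups, and 0 to 5 under JQ1 without JQ1_Veh a or b, siCont_E2 a or b, siCont_Veh b, or any 1 siBRD4 library.

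Between JQ1 and BRD4 siRNA, limma called no difference in the E2 responses of GREB1 and MYC with all 12 libraries. Without JQ1_E2 a, library b stands alone in its group, so only the sizes of differences are given for that fit. The E2 response of GREB1 was lower under JQ1 than under BRD4 siRNA by -2.06 (limma adjusted p = 0.13), and without JQ1_E2 a by -1.67. Against control, the GREB1 interaction with JQ1 was -1.87 ± 0.28 (adjusted p = 0.0708), and -1.48 without JQ1_E2 a. The MYC response was higher under JQ1 than under BRD4 siRNA by 0.99 (limma adjusted p = 0.389), and by 0.82 without JQ1_E2 a. In all 12 libraries limma called 0 genes for this difference, with 776 genes at an unadjusted p under 0.05, against 17 genes by DESeq2 and 0 by edgeR. With only the compared groups in the fit 0 genes were called, and with sample weights 1. Without JQ1_E2 a, KCNK5 differed by -1.67 and TFF1 by -1.10. With JQ1_E2 b left out instead, 8671 genes were called, with library a alone in its group.

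BRD4 siRNA in hormone-deprived cells raised interferon genes and lowered many mitosis, DNA replication and estrogen-induced genes. With 1 BRD4 siRNA treatment, effects of the siRNA duplexes and of the loss of BRD4 cannot be told apart. IFI44L and OAS2, which viral RNA sensors and interferon switch on, rose strongly, while the insulin-like growth factor binding protein gene IGFBP5 fell to a few percent of its level and TOP2A, SPDEF and ESR1 fell. BRD4 is thought to hold P-TEFb at enhancer-driven genes, which in luminal breast cells include these receptor targets. In numbers, 3595 genes changed (limma), 1575 higher (43.8%) and 2020 lower, with 568 and 593 by at least 2-fold. With upper quartile scaling the larger side turned, with 1956 higher (52.5%) and 1767 lower. Without JQ1_E2 a, 8439 genes were called, 3761 higher and 4678 lower, which held 3588 of the 3595. Leaving out JQ1_E2 b gave 8450, and leaving out siCont_Veh a, siCont_Veh b, siBRD4_Veh a or siBRD4_Veh b gave 1599 to 1780.

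IFI44L rose from 14.9 to 563.2 normalised reads, by 5.18 ± 0.49, and OAS2 by 3.53 ± 0.29. IFI44 rose by 2.72, IFI27 by 2.39, the steroid-metabolising enzyme gene AKR1C3 by 2.99 and KIAA1683 by 3.05. The basal and contractile cell markers TP63 and ACTA2 went up from low levels by 2.18 and 2.24, in a list of other cell types with 3 up and 2 down (median -0.04). Of 25 interferon response genes 21 rose and 0 fell, 24 when adjusted over the list alone (median 1.47, 25 of 25 positive, camera adjusted p = 1.45e-17, and adjusted p = 0.134 with an estimated correlation). IGFBP5 fell from 6160 to 202.2, by -4.93 ± 0.17. The signalling inhibitor gene SPRY4 changed by -3.99, AOX1 by -3.32, HOPX by -3.30, LHX6 by -3.21, RGS2 by -2.98, the luminal transcription factor gene SPDEF by -2.46, the receptor kinase gene RET by -1.97 and NDRG1 by -1.90. Estrogen targets fell even without hormone, GREB1 by -1.63, TFF1 by -1.6, XBP1 by -1.49 and MYC by -0.56, in a list with 22 of 38 down and 1 up (26 when adjusted over the list alone, camera adjusted p = 2.41e-08, and adjusted p = 0.134 with an estimated correlation).

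The mitosis list had 16 of 20 down and 0 up, 17 when adjusted over the list alone, with TOP2A at -1.70, KIF20A at -1.19 and CDK1 at -1.02 (camera adjusted p = 1.37e-11, and adjusted p = 0.134 with an estimated correlation). DNA replication had 17 of 21 down and 0 up, 19 when adjusted over the list alone, with RRM2 at -1.28 (camera adjusted p = 1.07e-11, and adjusted p = 0.134 with an estimated correlation). Ribosome biogenesis had 7 of 25 down, 8 when adjusted over the list alone, with NOLC1 at -0.92 (camera adjusted p = 4.01e-05, and adjusted p = 0.408 with an estimated correlation). The histone and BET-inhibitor list had 8 of 14 up and 2 down, HEXIM1 at -1.36 against HIST1H2BG at 1.92 (10 when adjusted over the list alone, camera adjusted p = 0.000268, and adjusted p = 0.346 with an estimated correlation). The luminal list had 3 of 14 down and 0 up, SPDEF, AGR2 at -1.39 and ESR1 at -0.85, and 6 called when adjusted over the list alone. Camera gave adjusted p = 0.359, and adjusted p = 0.715 with an estimated correlation, and the list's median changed sign with upper quartile scaling, from -0.06 to 0.01.

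With E2 present, BRD4 siRNA kept the same pattern, with more of the estrogen-induced and ribosome biogenesis genes called lower. More calls alone do not show a larger effect, and with all 12 libraries EGR3 was the 1 gene called for a differing E2 response. As a list, however, estrogen-induced genes were lowered more with E2, by a median difference of -0.48 that camera called with both correlations. The ribosome biogenesis list was called lower at the preset correlation only. EGR3, IGFBP4, PGR and CCND1, raised by the hormone in control cells, were lower, and so were MYC, SLC7A5 and SLC2A1. TXNIP and CCNG2 were higher. In numbers, 4351 genes changed (limma), 1898 higher (43.6%) and 2453 lower, with 721 and 719 by at least 2-fold. Of these, 1253 were also higher and 1633 also lower in vehicle, against 181 and 300 for independent lists, with r = 0.863 across genes between comparisons that share no library. Upper quartile scaling moved the median of all genes by 0.11 and the share of higher genes to 57.6%. Without JQ1_E2 a, 9141 genes were called, 3951 higher and 5190 lower, which held 4341 of the 4351. Leaving out JQ1_E2 b gave 9156, and leaving out siCont_E2 a, siCont_E2 b, siBRD4_E2 a or siBRD4_E2 b gave 2152 to 2229.

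IFI44L rose by 5.91, OAS2 by 3.78, IFI44 by 3.18, SLITRK5 by 3, ACTA2 by 2.70, TP63 by 2.42, KLHL24 by 1.80, TXNIP by 1.66 and CCNG2 by 1.17. The mesenchymal gene VIM rose by 3.64 ± 0.9 on uneven libraries, at 37.1 in a and 476.5 in b. IGFBP5 changed by -4.96, the imprinted RNA H19 by -3.65, RET by -3.11, SPRY4 by -3.05, VWF by -2.82, EGR3 by -2.78, SPDEF by -2.46, NDRG1 by -2.12, SLC7A5 by -1.97, IGFBP4 by -1.96, TFF1 by -1.84, SLC2A1 by -1.57, GREB1 by -1.44, PGR by -1.22, MYC by -1.05, CCND1 by -0.93 and ESR1 by -0.73. Of 38 estrogen-induced genes 31 fell and 0 rose, 31 when adjusted over the list alone (median -1.10, camera adjusted p = 2.59e-16, and adjusted p = 0.0503 with an estimated correlation). The estrogen-repressed list had 8 of 17 up and 3 down, 13 when adjusted over the list alone (camera adjusted p = 0.0303, and adjusted p = 0.168 with an estimated correlation). Ribosome biogenesis had 20 of 25 down and 0 up, 23 when adjusted over the list alone, with NOLC1 at -1.07 and POLR1B at -0.94 (camera adjusted p = 1.44e-10, and adjusted p = 0.147 with an estimated correlation). Interferon genes had 22 of 25 up, 25 when adjusted over the list alone (camera adjusted p = 2.1e-18). DNA replication had 17 of 21 down, 20 when adjusted over the list alone (camera adjusted p = 2.57e-08), and mitosis 13 of 20 down, 16 when adjusted over the list alone (camera adjusted p = 9.4e-07). Each of these 3 had adjusted p = 0.147 with an estimated correlation.

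JQ1 in hormone-deprived cells gave the known mark of BET inhibition, a rise of HEXIM1, SERPINI1 and histone genes, without a called change of MYC. ATF3, JUN and GADD45A rose, while the Wnt antagonist gene DKK1, the chemokine gene CCL2 and TGFB2, fell. HEXIM1 and SERPINI1 serve widely as readouts of the drug in treated cells. In numbers, 1176 genes changed (limma), 509 higher (43.3%) and 667 lower, with 209 and 224 by at least 2-fold. Without JQ1_E2 a, 4569 genes were called, 1984 higher and 2585 lower, which held 1174 of the 1176. Leaving out JQ1_E2 b gave 4574, and leaving out siCont_Veh a, siCont_Veh b, JQ1_Veh a or JQ1_Veh b gave 377 to 427.

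FCGR1B rose by 3.66, FCGR1A by 3.25, the scaffold gene AHNAK2 by 3.19, ADAMTSL4 by 3.14, HIST1H1B by 3.41, FAM126A by 2.69, SERPINI1 by 2.67, GADD45A by 1.91, HEXIM1 by 1.5, the elongation factor gene ELL2 by 1.42, ATF3 by 1, FOS by 0.94, JUN by 0.85 and BRD2 by 0.76. The FCGR1 and histone genes have near-identical copies and are uncertain one by one. DRD1 changed by -3.54, DKK1 by -2.93, SLITRK6 by -2.86, the fibrillin gene FBN2 by -2.54, CCL2 by -2.31, TP63 by -2.15, PSCA by -2.13, TGFB2 by -1.94, STC2 by -1.18, XBP1 by -0.73 and CCND1 by -0.48. MYC, at -0.07, and GREB1, at -0.37, were not called, and GREB1 was called without JQ1_E2 a (adjusted p = 0.000232). In the histone list 13 of 14 rose and 0 fell, 14 when adjusted over the list alone (median 1.04, camera adjusted p = 3.24e-21, and adjusted p = 0.0652 with an estimated correlation). Immediate-early genes had 5 of 21 up, 10 when adjusted over the list alone (camera adjusted p = 0.000217, and adjusted p = 0.141 with an estimated correlation). The BET family and P-TEFb list had 4 of 12 up, HEXIM1, ELL2, BRD2 and MEPCE, 5 when adjusted over the list alone (camera adjusted p = 0.00297, and adjusted p = 0.116 with an estimated correlation). Of 25 interferon genes 3 fell and 0 rose, SAMD9 at -1.38 and IFIT5 at -0.94 among them, 9 when adjusted over the list alone (camera adjusted p = 0.000217, and adjusted p = 0.481 with an estimated correlation).

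With E2, JQ1 lowered some receptor targets that the hormone raised in control cells, but not MYC. MYC stood at 13220 and 10500 normalised reads in JQ1_E2 a and b, against 8850 and 8655 in siCont_E2 a and b. GREB1, PGR, CXCL12, EGR3 and NRIP1 were lower than with E2 alone, HEXIM1 and the histone genes were higher. The blood, fat and stroma transcripts HBB, FABP4, CD36 and DCN lay beside them among the highest genes. DCN stood at 33.9 and 72.6 normalised reads against at most 5.67 in the other libraries. In numbers, 2158 genes changed (limma), 852 higher (39.5%) and 1306 lower, with 318 and 397 by at least 2-fold. Of these, 378 were also higher and 505 also lower in vehicle, against 26.3 and 52.8 for independent lists. Without JQ1_E2 a, 3879 genes were called, 1422 higher and 2457 lower, which held 2035 of the 2158. Without JQ1_E2 b the count was 10394, with library a alone in its group. It was 666 without siCont_E2 a and 609 without siCont_E2 b. With only the compared groups in the fit, where the spread of the JQ1_E2 pair is not shared with other groups, 1 gene was called, and with sample weights 292.

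Among all 12 libraries GREB1 changed by -2.24 (-1.85 without JQ1_E2 a), PGR by -2.44 (-1.93), CXCL12 by -2.43 (-2.47), EGR3 by -2.48 (-2.44), NRIP1 by -1.25 (-0.77), RBM24 by -2.95 (-2.84), DRD1 by -2.81 (-2.64), DKK1 by -2.71 (-3.05), VWF by -2.67 (-2.23) and ADM by -2.29 (-2.86). B3GALT5 changed by -3.05 (-2.15), NAV2 by -2.95 (-2.66), HEG1 by -2.70 (-2.17), CCL2 by -2.06 (-2.43), the survival gene BIRC3 by -1.43 (-1.44) and CCND1 by -0.78 (-0.67). TFF1, at -0.46, was not called, and its libraries stood at 2610 in a and 1023 in b. Without JQ1_E2 a it changed by -1.14. SERPINI1 rose by 3.39 (3.21), GADD45A by 2.23 (1.98), HEXIM1 by 1.91 (1.83), ELL2 by 1.38 (1.42), SESN2 by 1.13 (0.98), INSIG1 by 0.93 (0.85) and BRD2 by 0.66 (0.73). In the histone list 14 of 14 rose, 14 when adjusted over the list alone (median 1.19 with all libraries and 1 without JQ1_E2 a, camera adjusted p = 1.06e-16, and adjusted p = 0.0641 with an estimated correlation). Of 38 estrogen-induced genes 18 fell and 0 rose, 24 when adjusted over the list alone (camera adjusted p = 3.34e-11, and adjusted p = 0.0641 with an estimated correlation). Coregulators had 4 of 14 down, NRIP1 and CREBBP at -0.93 (-0.42 without JQ1_E2 a) among them, 6 when adjusted over the list alone (camera adjusted p = 0.00124, and adjusted p = 0.331 with an estimated correlation). Their median difference between the JQ1_E2 libraries, a minus b, was -0.86. NF-kB genes had 6 of 11 down, 6 when adjusted over the list alone (camera adjusted p = 0.00308, and adjusted p = 0.18 with an estimated correlation).

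**Figure D4:**
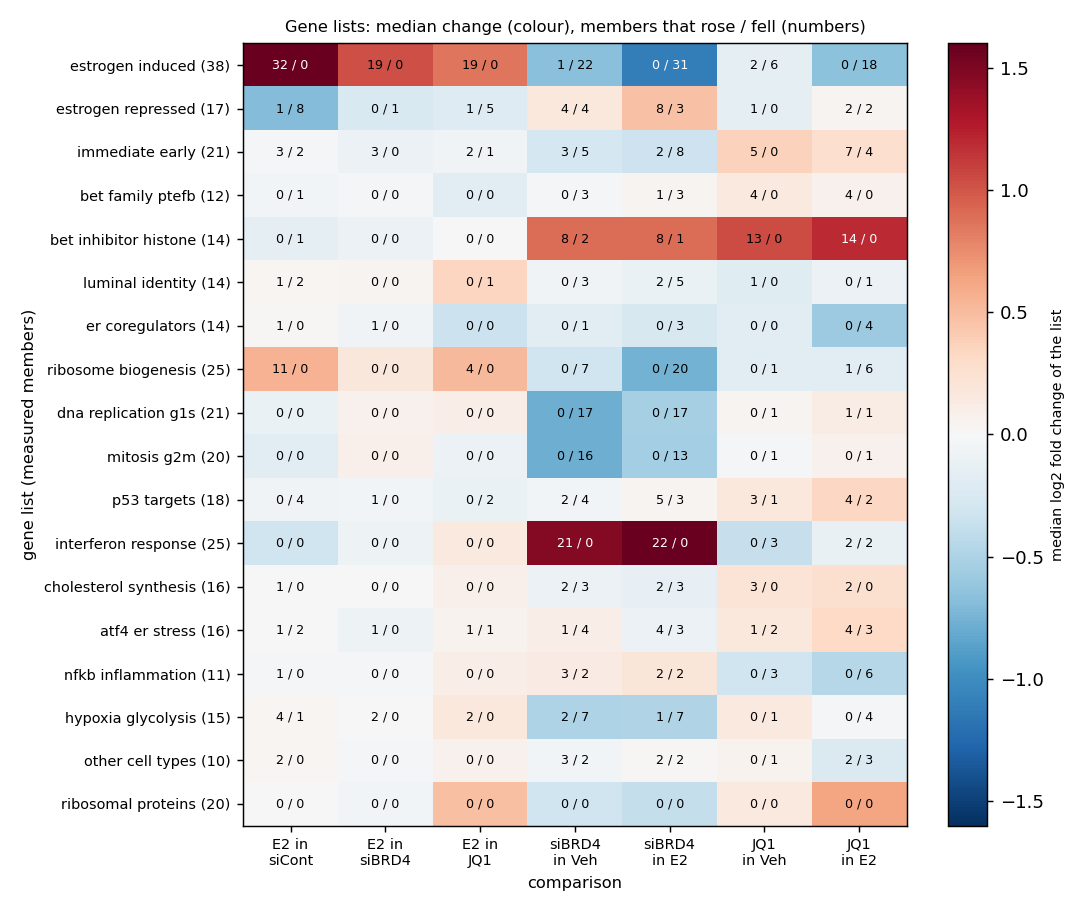
Median log2 fold change of each gene list (colour) and the number of its genes that rose and fell (numbers) in the 7 comparisons of 2 groups, all 12 libraries. Interferon genes are up under BRD4 siRNA and not under JQ1, and estrogen-induced genes are up with E2 and down with BRD4 siRNA. The median of luminal identity under BRD4 siRNA changes sign with upper quartile scaling.

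How far JQ1 resembled BRD4 siRNA was measured by overlap and correlation of the changes from control siRNA. Both changes subtract the same control libraries, which by itself raises shared calls in 1 direction above those of independent lists. In vehicle both raised 173 genes and lowered 211, against 48.6 and 81.7 for independent lists, and 69 and 61 moved in opposite directions, against 63.7 and 62.4. Without JQ1_E2 a they raised 767 and lowered 1029, against 453 and 734, and 529 and 526 moved in opposite directions, against 590 and 563. Under E2 both raised 300 and lowered 491, against 98.1 and 194, and 123 and 92 moved in opposite directions, against 150 and 127. Without JQ1_E2 a they raised 679 and lowered 1328, against 341 and 774. The correlation across genes was r = 0.23 under E2, with covariance 0.081, where unchanged groups with the same controls gave r = 0.5 and covariance 0.016. These draws used the spread of the fit without JQ1_E2 a. The JQ1_E2 pair varied more than that, so the r of 0.5 is not the level for unchanged groups with all 12 libraries. Without JQ1_E2 a r was 0.34, with covariance 0.1, where unchanged groups gave r = 0.41 and covariance 0.016, and without JQ1_E2 b r was 0.11. In vehicle r was 0.25, with covariance 0.064, where unchanged groups gave r = 0.5 and covariance 0.016. Real changes add variance that unchanged groups lack, so an r under the simulated one does not mean less likeness than by chance. The covariances can be compared. In vehicle the shared controls gave 0.016 of 0.064 in these draws, which left 0.048. Pairs without shared control libraries gave r = 0.15 both ways, with covariances of 0.049 and 0.04. Part of the excess of shared calls may come from the shared controls. Genes are not independent replicates, and no p-value was computed.

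Compared directly, in a contrast added after the data were seen, JQ1 and BRD4 siRNA differed in interferon, DNA replication and mitosis genes. JQ1 blocks bromodomains of the BET family, while the siRNA targets BRD4. JQ1 was added 30 min before E2, and the length of the siRNA treatment is not given here. In this contrast and in the overlaps, effects of the target and of the length of treatment cannot be told apart. In vehicle 4381 genes differed, 2270 higher under JQ1 and 2111 lower. Of 25 interferon genes 24 were lower under JQ1, and 14 of 21 DNA replication genes and 16 of 20 mitosis genes were higher. Each list had adjusted p = 0.121 with an estimated correlation. Under E2 6296 genes differed, 3480 higher and 2816 lower, with 20 of 25 interferon genes lower and 15 of 20 mitosis genes higher. TOP2A stood at 7610 in JQ1_Veh against 2538 in siBRD4_Veh. Without JQ1_E2 a the counts were 8920 in vehicle and 7716 under E2, and with sample weights 8174 and 2046.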

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

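Chosen after the results were seen were the direct contrast of JQ1 with BRD4 siRNA and the tests of transcript length as a part of the cause, of a mislabelled library, of uneven HBB, HBA1, HBA2, FABP4 and CD36 levels, of the JQ1 median of interferon genes and of the siRNA duplexes.

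Each result here is a difference between the effects of 2 treatments that passed a test of the difference itself. The E2 response of EGR3 was lower under BRD4 siRNA by -1.86 and under JQ1 by -2.17, and EGR3 was the 1 gene called under BRD4 siRNA. Under JQ1 9 genes were called. Besides EGR3, the transglutaminase gene TGM2 at -2.26, LOC100507584 at -2.72, HLA-DRB6 at -1.81, the Wnt receptor gene FZD7 at -1.57, FOS at -1.56 and MYBL1 at -1.55 responded less, while ANXA1 at 2.23 and HBB were called higher. HBB transcripts in JQ1_E2 may come from RNA of another tissue, so HBB is not read as an E2 response. ANXA1 stood at 122.3 and 130.7 in the same 2 libraries, against 33.1 and 41.49 in JQ1_Veh. Its mean was 148.2 in siBRD4_Veh and 140.7 in siBRD4_E2. Whether its rise in JQ1_E2 has the same origin was not tested, so ANXA1 is not read as an E2 response either. The fitted HBB value of 10.04 depends on the pseudocount, because both siCont_E2 libraries had 0 reads, and is no bound on its change. HLA-DRB6 has close paralogs, so its reads are uncertain. Camera at its preset correlation called 9 gene lists for the difference under BRD4 siRNA, 7 under JQ1 and 3 between JQ1 and BRD4 siRNA. With an estimated correlation 2 stayed, both under BRD4 siRNA: estrogen-induced genes, with a median of -0.48, and estrogen-repressed genes, with a median of 0.45. Compared directly, 4381 genes differed between JQ1 and BRD4 siRNA in vehicle and 6296 under E2. Without JQ1_E2 a the counts of genes were 644 under BRD4 siRNA, 162 under JQ1, 8920 directly in vehicle and 7716 directly under E2. With sample weights the direct counts were 8174 in vehicle and 2046 under E2. The calls of single genes depend on which libraries and groups enter the fit. With a replicate block by column letter, or with no filter on low values, 0 genes were called under BRD4 siRNA. Under BRD4 siRNA 0 genes were called without any 1 library outside JQ1_E2. Under JQ1 0 were called without siCont_Veh b, siCont_E2 a, siCont_E2 b or JQ1_Veh a, 3 with sample weights and 1 with only the compared groups in the fit.

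Library JQ1_E2 a stood apart from its partner. Removing smooth trends on transcript length and GC content left the SD of their log2 difference at 0.606, from 0.702, against 0.226 to 0.245 in the other pairs, which argues against these trends as the whole cause. A wrong label is argued against by its correlation over 2000 genes, higher with its partner than with any other group by 0.15. A bias by transcript length may be a part of the cause, since the difference followed length with rho = -0.4, outside the -0.08 to -0.15 of the other pairs. What caused the rest stays open, and no biological explanation was tested.

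Blood, fat and stroma transcripts rose in both JQ1_E2 libraries and may come from RNA of another tissue. Of 28 further markers with low background, 11 lay above all other libraries in both, 17.2 times the number for random genes of like level (one-sided permutation p = 1e-04, the smallest that 10000 random lists can give). The 5 first genes were not higher in library a (median a minus b -0.59), so its distortion is not their origin. Markers of 4 separate tissue lists passed 3 times the number for random genes, 3 of the lists at p under 0.05. Endothelium passed with 1 of 7 markers (one-sided permutation p = 0.17). With 0.116 to 0.225 genes expected per list, 1 gene is enough to pass, so a response to JQ1 with E2 is not excluded. The most abundant were FABP4 at 388.4 and 583.5 and HBB at 363.7 and 575.3, while ADIPOQ, at 79.1 and 152.4, reached up to 130 elsewhere, PTPRC was at 0, and 27 more of the 55 markers have background in MCF7. How such RNA entered the libraries was not tested.

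Under BRD4 siRNA in vehicle 21 of 25 interferon genes rose. The scaling of the libraries is argued against, since the lower of the list's medians under TMM and upper quartile scaling was 1.49. A loss of bromodomain binding that acts within the time of JQ1 treatment is argued against as well, with a median of -0.37 under JQ1 in vehicle. A response to the siRNA duplexes and a response to the longer loss of BRD4 protein cannot be told apart, because the median of 1.47 comes from a design with 1 BRD4 siRNA treatment. Both may apply.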

How the results depend on the processing

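Chosen after the data were seen were sample weights, a replicate block by column letter, removal of a trend with transcript length, list tests without JQ1_E2 a and the vehicle correlation. The planned replicate block uses the replicate numbers of the titles, which were not matched to the column letters, so the letters stood in for it. Differences between libraries a and b correlated at r = 0 to 0.27 over 15 pairs of groups, with 8 over 0.1. These values do not scatter to both sides of 0, so libraries of 1 letter may share a difference that the main fit does not model. What the letters mark is not stated. With this replicate block the response differed for 0 genes under BRD4 siRNA, 9 under JQ1 and 1 between them. Counts were 642 for E2 in control siRNA, 3895 for BRD4 siRNA in vehicle and 2374 for JQ1 under E2.

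The fall of BRD4 mRNA and the negative medians of E2-induced genes kept their direction under every alternative. In most of these the same control libraries chose the genes and entered the difference, which favours a negative median. Genes chosen on control libraries of 1 letter were also measured against the other letter. Their medians were -0.58 and -0.55 under BRD4 siRNA, and -0.54 and -0.47 under JQ1. The fixed list gave -0.48 and -0.47. The counts of genes rest on how the spread of the JQ1_E2 pair is treated. Leaving out each library in turn gave 236 to 2809 genes for E2 in control siRNA, 39 to 522 for E2 under BRD4 siRNA, 56 to 10122 for E2 under JQ1, 1599 to 8450 for BRD4 siRNA in vehicle, 2152 to 9156 for BRD4 siRNA under E2, 377 to 4574 for JQ1 in vehicle and 609 to 10394 for JQ1 under E2. The E2 response differed for 0 to 644 genes under BRD4 siRNA, 0 to 8441 under JQ1 and 0 to 8671 between them. BRD4 ranged from -1.81 to -1.75, the median under BRD4 siRNA from -0.66 to -0.56, that under JQ1 from -0.67 to -0.48 and the correlation from 0.11 to 0.34. Camera's calls of a list, counted over all 10 comparisons, ranged from 61 to 84, against 69 with all libraries. Leaving out either JQ1_E2 library removes the difference within that pair from the pooled spread. Without b, library a stands alone and its distance from all groups enters the calls, which gave the highest counts for JQ1_E2. A lone library was assumed to vary like the other groups.

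With only the compared groups in the fit, counts were 3226 for E2 in control siRNA, 533 for E2 under BRD4 siRNA, 3 for E2 under JQ1, 8224 and 9632 for BRD4 siRNA in vehicle and under E2, 4574 for JQ1 in vehicle and 1 for JQ1 under E2, and the response differed for 649 genes under BRD4 siRNA and 1 under JQ1. Sample weights, which give both libraries of a group 1 weight, gave 3146, 473, 41, 8106, 9728, 4342 and 292 in the same order, and differences for 657, 3 and 1 genes under BRD4 siRNA, under JQ1 and between them. In both, groups other than JQ1_E2 no longer carry its spread. DESeq2 gave 149 genes for E2 under BRD4 siRNA, 594 for E2 under JQ1, and differences for 66, 62 and 17 genes.

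The response differed under BRD4 siRNA for 0 genes with no filter, 3 with TMM, 3 with upper quartile scaling, 2 without the eBayes trend and 3 with the length trend removed. Under JQ1 it differed for 19 genes with pseudocount 5, 18 without the eBayes trend and 16 with the length trend removed, and between treatments for 3 genes with pseudocount 5. The median under BRD4 siRNA was -0.55 with upper quartile scaling, -0.55 with genes chosen on libraries b and measured against a, -0.48 in the fixed list and -0.75 for genes at least 2-fold higher. Under JQ1 it was -0.58 with no filter, -0.47 at a mean of at least 50, -0.54 without the trend, -0.55 with the compared groups alone, -0.47 chosen on b and measured against a, -0.79 for genes at least 2-fold higher and -0.55 with weights. Of 69 calls of a list, counted over all 10 comparisons, 7 remained with an estimated correlation. Upper quartile scaling moved the median of all genes under BRD4 siRNA with E2 by 0.11. Of 380 list medians under both scalings 11 changed sign, none of them beyond 0.1 with the authors' scaling. For these shifts the cause was not tested.

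Of 12150 values of named genes over 25 alternatives, 11109 kept direction and side of the threshold, 943 lost their call, 89 gained one and 9 reversed. All 9 arose from leaving out 1 JQ1_E2 library, where the libraries themselves differ. BRD3 lay between -0.5 without b and 0.04 without a for E2 under JQ1, between -0.44 and 0.1 for JQ1 under E2, and between -0.52 and 0.02, and -0.46 and 0.08, for the difference under JQ1 and between treatments. GREB1 lay between -0.38 without b and 0.4 without a for E2 under JQ1. TFF1 lay between -0.05 without a and 1.3 without b for E2 under JQ1, between -1.14 and 0.21 for JQ1 under E2, and between -1.33 and 0.02, and -1.1 and 0.25, for the differences.

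Depth was 20969671 to 32899564 reads per library. In simulated counts with 1 library of extra spread, the test recovered 13.4% of genes changed by 1.5-fold against 79.1% with all libraries alike, so small changes missing from the 12-library counts are not shown to be absent.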

Other observations

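The test of histone neighbours was chosen after the result was seen, and the direct contrasts of JQ1 with BRD4 siRNA were added after the data were seen.

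Some genes of glucose use and oxygen shortage fell under BRD4 siRNA. NDRG1 fell by 1.90 and PDK1 by 1.02 in vehicle, in a hypoxia and glycolysis list with 7 of 15 genes down and 2 up (10 when adjusted over the list alone, camera adjusted p = 0.00112, and adjusted p = 0.181 with an estimated correlation). With E2 the list had 7 down and 1 up, 8 when adjusted over the list alone (camera adjusted p = 0.000191, and adjusted p = 0.147 with an estimated correlation). JQ1 in vehicle lowered 1 of the 15, EGLN3, by -1.02, and camera did not call the list (adjusted p = 0.51). In the direct contrast in vehicle 9 of the 15 were higher under JQ1 than under BRD4 siRNA and 1 was lower.

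JQ1 raised some sterol genes and lowered some inflammatory ones. INSIG1 rose by 0.86 and the receptor gene LDLR by 0.64 in vehicle, with 3 of 16 cholesterol synthesis genes up and 0 down (4 when adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.141 with an estimated correlation). In the NF-kB and inflammation list CCL2 fell by 2.31, with 3 of 11 down and 0 up (5 when adjusted over the list alone, camera adjusted p = 0.00406, and adjusted p = 0.141 with an estimated correlation). The p53 targets had 3 of 18 up, GADD45A among them, and 1 down, GDF15 at -0.94 (5 when adjusted over the list alone, camera adjusted p = 0.0436, and adjusted p = 0.141 with an estimated correlation). The ATF4 and endoplasmic reticulum stress list split, with TRIB3 at -1.20 and 1 of 16 up and 2 down (4 when adjusted over the list alone, camera adjusted p = 0.511, and adjusted p = 0.847 with an estimated correlation). The list of other cell types had 1 of 10 down, TP63, and 0 up (1 when adjusted over the list alone, camera adjusted p = 0.949, and adjusted p = 0.971 with an estimated correlation). Mitochondrial mRNA was measured by 2 genes, with 0 called by limma in each of the 7 comparisons of 2 groups.

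The FCGR1 genes, which rose with JQ1, lie next to histone genes, and a candidate explanation is that transcription or reads run on from histone genes into their neighbours. Of 11 other neighbours of replication-dependent histone genes, 5 rose with JQ1 in vehicle without JQ1_E2 a, against 11.7% of the remaining genes (Fisher's exact test, one-sided, p = 0.0056). Without OR2B6, which had been seen before the test, 4 of 10 rose (the same exact test, p = 0.022). GUCY2C rose by 5.14 ± 0.58, OR2B6 by 1.86, OR2B2 by 1.37, BOLA1 by 0.88 and HFE by 0.83, while GUSBP2 changed by -0.57 and WBP11 by -0.29. A gene low in control cells could pass the filter on the mean through the JQ1 libraries, while silent neighbours that did not rise were left out. The exact test also counts genes of 1 locus as independent, so its p-values are rough. Without strand or read positions, run-on reads and a rise of each neighbour's own transcript stay open.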
